A study of Caenorhabditis elegans with 9 samples.

How the data were processed

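RNA was taken from whole animals on day 1 of adulthood in 9 samples, 3 each of wild type, micu-1 and micu-1;mcu-1, as the sample labels give them. Per the labels, animals were obtained by bleaching and grown on plates seeded with OP50, RNA was extracted with Trizol and column purification, and libraries were made by SMART-seq2 with tagmentation. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20 and quantified with kallisto 0.44.0 against transcripts of WBcel235. The release of the transcript annotation was not given.

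The deposited tables hold, for each transcript, estimated counts and length-scaled TPM values as made by the authors with kallisto. The deposited estimated counts were used for all values, and the deposited TPM only in the alternative with length offsets. Each table has 61451 transcripts under numeric identifiers. The deposited table that links transcripts to genes has 1 distinct value in its transcript-name column, so identifiers were taken as line numbers of that table, counted from 0. This join was checked on transcript lengths. Of 25286 non-coding transcripts, 99.96% had exactly the length of their gene's annotated transcript, against 58.64% when shifted by 1 line. Of 33895 protein-coding transcripts, 90.51% lay within 25% of an annotated length, against 50.88% when shifted. Counts were summed over the transcripts of each of 46904 genes and rounded. Gene names and positions came from the Ensembl 115 annotation of WBcel235, which holds 46817 of these genes. In it, 628 symbols belong to more than 1 gene. The effective length was the length less 74 bases in all 9 tables. The tables carry no strand information, so reads of genes that overlap on opposite strands may be shared between them.

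The total estimated count per sample ranged from 12674470 to 19047383. A floor of 3 counts over the group was used where all samples of a group had 0 counts, and 95% exact Poisson intervals of the lower count where a group had 1 to 3 counts. Both cover counting error only.

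Before the data were examined, the groups, comparisons, gene lists, tests and most alternatives were fixed. The comparisons were micu-1 against wild type, micu-1;mcu-1 against micu-1 and micu-1;mcu-1 against wild type. One model of all 9 samples was fitted with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with TMM scaling, robust dispersions and the filter of filterByExpr (minimum count 10, minimum total 15), which left 14551 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Tests were two-sided. Counts were simulated with the mean of each gene over all samples, the depths and dispersions of the data, and 200 changed genes. On these, edgeR recovered 51 to 56% of genes with a log2 change of 1 and 86 to 88% with a log2 change of 2. It called 11 unchanged genes in each comparison. In the real comparisons with wild type, 12289 and 12201 of 14551 genes were called. The simulation therefore did not test the method or TMM scaling where most genes change.

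There were 37 gene lists, written from general knowledge of gene function and named where their results are given, of which 36 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with a correlation estimated per list, and with fry. Camera compares a list with all other genes, while fry asks only whether the members move one way on balance. Members were also counted with p adjusted over the list alone. These counts are given where they differ from the counts over all genes. The symbols first written for mitochondrial protein-coding genes were absent from the annotation, so those genes were matched by chromosome and gene type after values had been seen.

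Named genes were chosen by a rule. In each comparison it names, first, micu-1 and mcu-1. Second, among genes with adjusted p under 0.05, no overlap between the CPM of the 3 and 3 samples and a mean CPM over 9 samples of at least 5, it names the 10 largest log2 fold changes in each direction among genes with a class symbol and the 2 largest among genes with a sequence name. Next, it names from each list the called members with the smallest adjusted p, at most 4, or, where none is called, at most 2 with the highest mean CPM. It always names spl-1, vps-39, lgg-1, sqst-1, bec-1, hlh-30, hsp-6, hsp-60, hsp-4 and gst-4. The text names fewer, from the top of each part.

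The alternatives were RLE size factors, total counts only, length offsets, no filter on low counts, a filter at a CPM of 5 in 3 samples, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, and leaving out each sample. After the data were seen, 3 were added. These left out ribosomal RNA genes, used total counts without ribosomal RNA genes, and summed copies that share a symbol. Sensitivity to shared control samples was tested in 20 simulations. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9. No sample was left out. Genes under the filter and 1 list with under 5 tested members were not tested.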

Results

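Transcript levels were measured by RNA sequencing of whole Caenorhabditis elegans on day 1 of adulthood. Populations of this nematode consist almost entirely of self-fertile hermaphrodites, which make sperm as larvae and oocytes as adults. The animals were grown on agar plates with the bacterium OP50 as food, and full-length cDNA was made from small amounts of total RNA by SMART-seq2 and fragmented by tagmentation. The 9 samples fell into 3 groups of 3. These were wild type, a micu-1 mutant with the allele bon20, and a micu-1;mcu-1 double mutant that also carried the allele ju1154 of mcu-1. The gene mcu-1 encodes the pore of the mitochondrial calcium uniporter, and micu-1 encodes a calcium-sensing regulator of that pore. The series title concerns MICU1 in autophagic flux and names SPGL1 and VPS39. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples.

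The total estimated count per sample was 13662364, 14629342 and 17628377 in wild type, 19047383, 13856431 and 15231761 in micu-1, and 18686303, 12674470 and 13705642 in micu-1;mcu-1. Between 16290 and 18193 genes had a count in each sample, and 14551 genes were tested. Values below are CPM, which are counts scaled to a common library size with TMM factors, as the mean ± SD with n = 3, and log2 fold changes with the SE of the fit. The reads carry no molecular identifiers, so intervals and floors cover counting error only.

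Ribosomal RNA genes took 9.89 to 13.7% of the counts in wild type, 24.04 to 27.9% in micu-1 and 28.7 to 43.7% in micu-1;mcu-1. Protein-coding genes of the mitochondrial genome took 0.891 to 1.40%, 3.01 to 3.78% and 2.39 to 4.59%, in the same order. Scaling by total counts in place of TMM moved the median log2 fold change of all genes by -0.49 for micu-1 against wild type, -0.22 for micu-1;mcu-1 against micu-1 and -0.71 for micu-1;mcu-1 against wild type. Total counts without ribosomal RNA genes moved it by -0.25, -0.04 and -0.29, and a filter at a CPM of 5 in 3 samples moved it by 0.32, -0.03 and 0.29. The first principal component held 89.9% of the variance and separated wild type from both mutants, and the second held 2.51%. Across genes, which are not independent replicates, log2 CPM of wild-type and micu-1 samples correlated with r = 0.576 to 0.586, and micu-1 with micu-1;mcu-1 samples with r = 0.958 to 0.966. Within groups, r was 0.980 to 0.982 in wild type, 0.978 to 0.979 in micu-1 and 0.962 to 0.971 in micu-1;mcu-1. The last of these ranges overlaps that between the mutants. For the counts of replicate pairs, chi-square per degree of freedom was 8.011 to 17.48 in wild type, 5.857 to 10.33 in micu-1 and 19.36 to 63.86 in micu-1;mcu-1. These values were scaled by total counts, so they also carry unequal shares of ribosomal RNA. The fit used a common spread per gene for all groups, so p-values of comparisons with micu-1;mcu-1 may be too small.

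**Figure D1:**
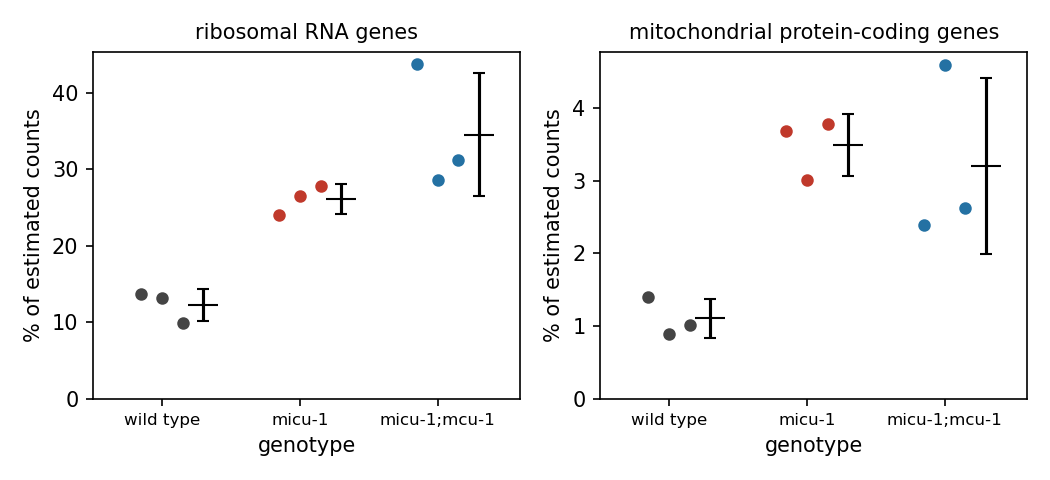
Share of the estimated counts of each sample (percent, linear axis from 0) taken by ribosomal RNA genes and by protein-coding genes of the mitochondrial genome, with 1 dot per sample and the mean ± SD of each group. Ribosomal RNA genes took 9.89 to 13.7% in wild type and 24.04% or more in every mutant sample.

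The transcripts of the mutated genes were read first. In the WBcel235 genome, micu-1 (WBGene00013462) lies on chromosome IV from 13297926 to 13300066, and mcu-1 (WBGene00019296) on the same chromosome from 5937447 to 5939230. The micu-1 level was 78.0 ± 4.79 CPM in wild type, 1.57 ± 0.525 in micu-1 and 2.19 ± 0.824 in micu-1;mcu-1. It was lower than wild type in micu-1 (log2 fold change -5.62, SE 0.21, adjusted p = 1.61e-15) and in micu-1;mcu-1 (-5.15, SE 0.21, adjusted p = 7.16e-15), with no overlap between samples. The mutants did not differ from each other in micu-1 (0.46, SE 0.28, adjusted p = 0.374). The mcu-1 level was 40.6 ± 4.80 CPM in wild type, 34.2 ± 1.79 in micu-1 and 16.8 ± 4.09 in micu-1;mcu-1. It was lower in micu-1;mcu-1 than in micu-1 (-1.02, SE 0.16, adjusted p = 0.000203) and than in wild type (-1.27, adjusted p = 2.44e-07). Between micu-1 and wild type, mcu-1 was not called (-0.25, SE 0.15, adjusted p = 0.128), but 5 of 21 alternatives called it lower, with adjusted p from 0.000555 to 0.653 over all of them. Among these, leaving out micu-1;mcu-1 replicate 3 gave -0.25 with adjusted p = 0.0492.

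**Figure D2:**
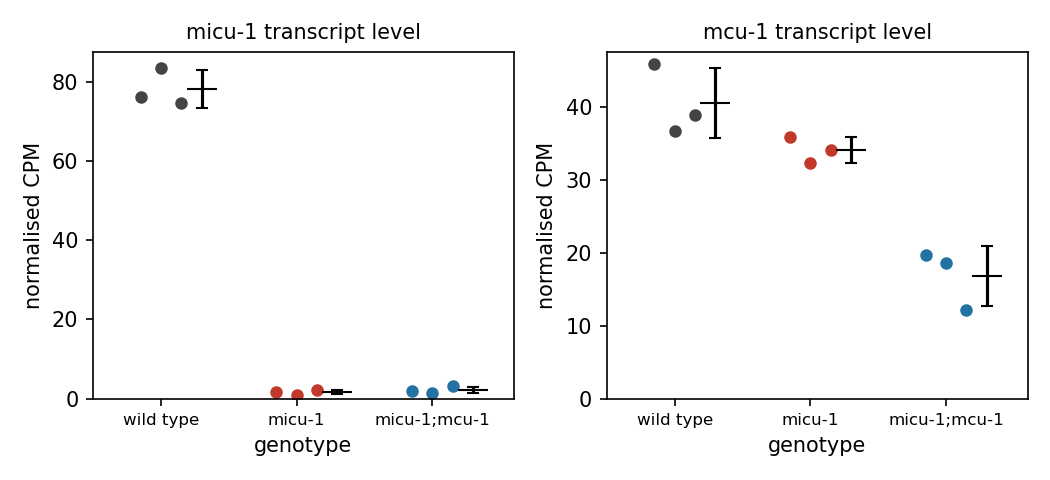
Level of micu-1 and mcu-1 transcripts in each sample (TMM-scaled CPM, linear axis from 0), with the mean ± SD of each group. The micu-1 level was 78.0 ± 4.79 in wild type and at most 2.19 ± 0.824 in the mutants, and mcu-1 was lowest in micu-1;mcu-1, at 16.8 ± 4.09.

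The comparison of micu-1 with wild type addressed how loss of the uniporter regulator changes gene expression, including genes of autophagy. Sperm genes were far higher in micu-1, while genes of oocytes, eggshell and early embryos were far lower. By camera, the lists of proteasome, autophagy and endosome-lysosome fusion genes were lower. With an estimated correlation, only autophagy was called (adjusted p = 0.0749, 0.0497 and 0.195). Whether these falls follow from the smaller share of oocyte and embryo transcripts was not tested. The lists of muscle, neuronal, cuticle collagen, detoxification and respiratory chain genes were called higher by camera. With an estimated correlation, only detoxification was (adjusted p = 0.256, 0.195, 0.409, 0.0497 and 0.256). By the edgeR quasi-likelihood test at an adjusted p under 0.05, 12289 of 14551 genes were called, 6718 higher and 5571 lower, and 10576 of them changed over 2-fold. With total counts only, the balance turned to 5542 higher and 6328 lower. The samples of both groups did not overlap for 12104 of these calls, and for 86.79% of tested genes, where chance gives 10%. Of 36 gene lists, 26 were called with camera at a preset correlation, 17 higher and 9 lower, but 2 with an estimated correlation.

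The 80 tested sperm genes summed to 177 ± 3.60 CPM in wild type and 12664 ± 1057 in micu-1. Of these, 74 were higher and 4 lower, or 74 and 5 adjusted over the list alone. Their median log2 fold change was 9.56, or 8.90 with genes at 0 counts in wild type set to their bound (camera adjusted p = 4.24e-15; adjusted p = 0.0721 with an estimated correlation). The 10 largest increases among genes with a class name were msp-51, ssp-9, msp-65, msp-56, msp-53, spch-3, msp-81, nspd-2, sss-1 and nsph-3.2. The major sperm protein genes (msp) form the moving skeleton of nematode sperm and include near-identical copies, so the level of any single copy, as for ssp-9 and nspd-2, is uncertain. The 31 msp genes together had 3.21 to 3.37 CPM in the wild-type samples and 9579 to 11437 in the micu-1 samples. By the list's smallest adjusted p, msp-113 rose from 0.0813 to 557 CPM and msp-33 from 0.189 to 682. The sperm chromatin gene spch-3 and sss-1 had 0 counts in wild type and were at least 3248-fold and at least 2260-fold higher, against a floor of 3 counts over the group. The gene msp-51 was at least 13510-fold higher.

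All 26 tested genes of oocytes, eggshell and germline were lower in micu-1, and their sum fell from 23178 ± 752 to 3724 ± 206 CPM. Their median log2 fold change was -4.66 (camera adjusted p = 5.29e-11; adjusted p = 0.139 with an estimated correlation). The RNA-binding protein gene puf-5 fell from 873 ± 49.3 to 15.7 ± 1.75 CPM (log2 fold change -5.80, SE 0.13, adjusted p = 1.12e-18). The egg surface gene egg-1 fell from 578 to 11.02 CPM, the chondroitin proteoglycan gene cpg-1 from 2408 to 52.7, and the maternal regulator pos-1 from 559 to 11.6. Of 12 early embryo genes, 10 were lower, with a median of -6.46, or -5.46 with genes at 0 counts at their bound (camera adjusted p = 0.00066; adjusted p = 0.119 with an estimated correlation). Among them, vet-2 fell from 58.0 ± 8.58 to 0.0977 ± 0.108 CPM. Of 51 histone genes, 33 were lower and 12 higher, with a median of -2.92 (camera adjusted p = 0.00815; adjusted p = 0.409 with an estimated correlation). Histone copies such as his-68, at 53.3 against 1.98 CPM, are near-identical and uncertain singly, while the H1 gene his-24 fell from 324 to 7.68 CPM. At the top of the decreases, rgs-9 and skr-7 had 0 counts in micu-1, which put them at least 669.5-fold and at least 410.3-fold lower. The autophagy receptor gene sepa-1 also had 0 counts there and was at least 562.5-fold lower.

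**Figure D3:**
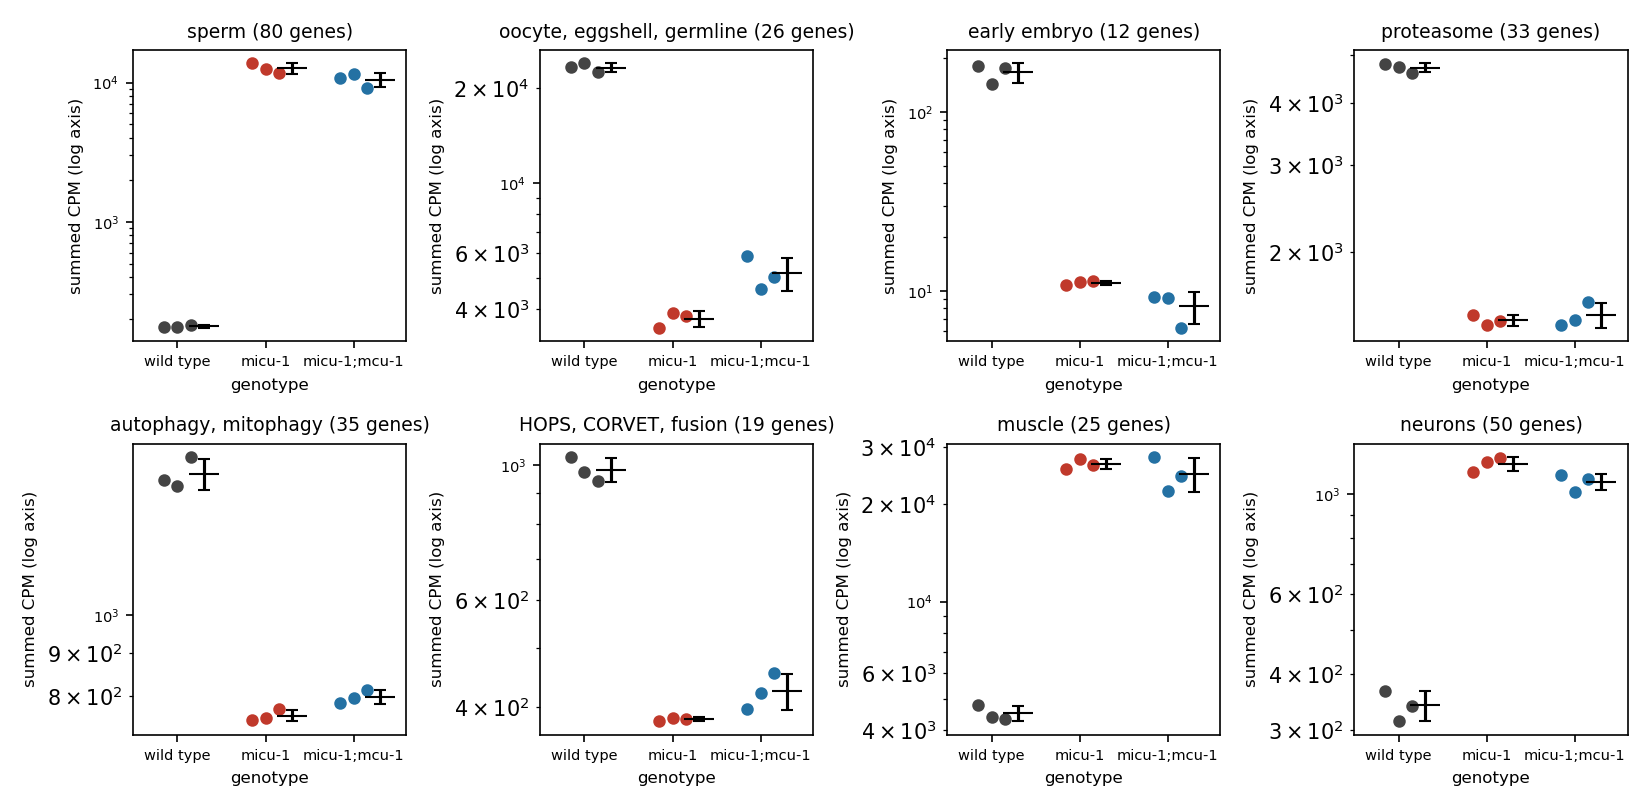
Summed CPM of 8 gene lists in each sample (TMM-scaled, log axis), with 1 dot per sample and the mean ± SD of each group. Sperm genes had 177 ± 3.60 CPM in wild type and 12664 ± 1057 in micu-1, and oocyte genes 23178 ± 752 and 3724 ± 206, with micu-1;mcu-1 at 10479 ± 1246 and 5179 ± 635.

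Of 35 genes of autophagy and mitophagy, 28 were lower and 2 higher in micu-1, or 30 and 2 adjusted over the list alone. Their sum fell from 1468 ± 62.7 to 759 ± 11.9 CPM and their median log2 fold change was -1.21 (camera adjusted p = 3.61e-05; adjusted p = 0.0497 with an estimated correlation). After sepa-1, the smallest adjusted p values belonged to atg-18, which fell from 119.1 ± 7.87 to 34.1 ± 3.04 CPM, epg-6, from 42.7 to 8.56, and vps-15, from 96.5 to 32.8. The initiation gene bec-1 was lower (-0.95, adjusted p = 4.3e-06). The ubiquitin-like gene lgg-1 was lower too (-0.41, adjusted p = 0.00326), but not with a filter at a CPM of 5 in 3 samples (-0.09, adjusted p = 0.464, range over its alternatives 1.13e-05 to 0.464). Higher were the receptor gene sqst-1 (0.64, adjusted p = 0.000336) and the transcription factor gene hlh-30 (0.58, adjusted p = 0.000226). Neither was called with total counts only, which gave 0.13 with adjusted p = 0.506 for sqst-1 (range 2.16e-06 to 0.506) and 0.08 with adjusted p = 0.69 for hlh-30 (range 2.03e-06 to 0.69).

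Endosome-lysosome fusion genes were lower in 17 and higher in 1 of 19 cases, and their sum fell from 982 ± 44.95 to 382 ± 2.81 CPM. The median was -1.19 (camera adjusted p = 0.00022; adjusted p = 0.195 with an estimated correlation). The tethering gene vps-39 (chromosome V) fell from 169 ± 7.55 to 30.9 ± 3.04 CPM (log2 fold change -2.45, SE 0.13, adjusted p = 6.28e-13), with no overlap between samples. Next in the list were vps-33.2, from 86.3 to 15.9 CPM, the lysosomal channel gene cup-5, from 85.8 to 19.1, and the RAB-7 activator gene sand-1, from 44.0 to 7.70. The lyase gene spl-1, which ends sphingolipid breakdown, had 61.4 ± 4.78 CPM in wild type and 55.3 ± 5.08 in micu-1 (-0.15, SE 0.11, adjusted p = 0.212). It was called lower with total counts only (-0.65, adjusted p = 0.000676) and with total counts without ribosomal RNA genes (-0.40, adjusted p = 0.00252, range over its alternatives 0.000676 to 0.514). Of 25 sphingolipid genes, 14 were higher and 5 lower, with a median of 0.93 (camera adjusted p = 0.287). The members with the smallest adjusted p, fath-1 and cgt-3, were lower, from 77.6 to 14.9 and from 117 to 37.3 CPM.

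Lysosomal hydrolases were mostly higher, 20 against 3 of 24, with a median of 1.09 (camera adjusted p = 0.0111; adjusted p = 0.333 with an estimated correlation). The cathepsin B-like gene cpr-1 was an exception and fell from 411 to 32.97 CPM, while the aspartyl protease gene asp-5 rose from 354 to 1042. Of 21 genes of the vacuolar proton pump, 15 were higher and 3 lower, or 16 and 3 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 0.041; adjusted p = 0.438 with an estimated correlation). That call was lost in 5 of 14 alternatives, among them those without wild type replicate 2 (adjusted p = 0.0562) and without wild type replicate 3 (adjusted p = 0.0735, range 0.00709 to 0.108). The apical pump gene vha-6 rose from 108 to 503 CPM, and vha-5 from 32.8 to 122.

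Proteasome subunit genes were lower in 32 and higher in 1 of 33 cases, and their sum fell from 4720 ± 100 to 1459 ± 35.98 CPM. The median was -1.68 (camera adjusted p = 4.57e-09; adjusted p = 0.0749 with an estimated correlation). The lid gene rpn-9 fell from 143 ± 2.07 to 27.6 ± 4.06 CPM and the ubiquitin receptor gene rpn-13 from 132 to 32.8. Genes of the ER unfolded protein response were lower in 10 of 13 cases, with a median of -0.82 (camera adjusted p = 0.00815; adjusted p = 0.208 with an estimated correlation), a call lost with the filter at a CPM of 5 (adjusted p = 0.111, range 0.00376 to 0.111). The ER chaperone gene hsp-4 fell from 302 ± 4.40 to 87.7 ± 3.69 CPM (-1.78, adjusted p = 1.1e-10). Of 14 heat shock genes, 6 were higher and 6 lower, and their median of -0.12 and mean of 0.55 differed in sign (camera adjusted p = 0.59). The co-chaperone genes sti-1 and dnj-13 fell from 128 to 22.3 and from 115 to 39.4 CPM. Mitochondrial unfolded protein response genes were higher in 7 and lower in 1 of 14 cases, with a median of 0.30 that turned to -0.20 with total counts only (camera adjusted p = 0.293), and the filter at a CPM of 5 called it higher (0.0441, range 0.0441 to 0.616). In that list, trx-2 rose from 6.77 to 21.7 CPM. The mitochondrial chaperone genes hsp-6 (0.22, adjusted p = 0.068) and hsp-60 (-0.01, adjusted p = 0.94) were not called. For hsp-60, total counts only gave -0.50 (adjusted p = 0.00437), total counts without ribosomal RNA genes -0.26 (0.0337) and the filter at a CPM of 5 0.31 (0.0101, range 0.00437 to 0.993). For hsp-6, 4 of 21 alternatives called it higher, among them those without micu-1;mcu-1 replicate 2 (0.22, adjusted p = 0.0481) and replicate 3 (0.22, adjusted p = 0.043, range 0.000128 to 0.821).

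Cytosolic ribosomal protein genes were lower in 42 and higher in 3 of 82 cases, or 35 and 3 adjusted over the list alone. Their median of -0.26 turned to 0.05 with the filter at a CPM of 5, where adjusted p = 0.738 in a range of 9.76e-05 to 0.738 (camera adjusted p = 0.00755; adjusted p = 0.629 with an estimated correlation). The copy rpl-11.2 rose from 107 to 351 CPM. Mitochondrial ribosomal protein genes were lower in 40 and higher in 3 of 70 cases, or 37 and 2 adjusted over the list alone, with a median of -0.55 (camera adjusted p = 0.00066; adjusted p = 0.208 with an estimated correlation). The filter at a CPM of 5 ended that call (adjusted p = 0.151, range 5.72e-05 to 0.151). The member with the smallest adjusted p was mrpl-34, which fell from 12.8 to 3.89 CPM.

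All 25 muscle genes were higher in micu-1, and their sum rose from 4511 ± 251 to 26609 ± 928 CPM. The median was 2.57 (camera adjusted p = 3.3e-07; adjusted p = 0.256 with an estimated correlation), with the troponin gene mup-2 at 39.2 ± 3.34 and 300 ± 9.15 CPM and the myosin gene myo-3 at 27.1 and 254. Of 50 neuronal genes, 43 were higher and 1 lower, with a median of 1.86 (camera adjusted p = 2.81e-05; adjusted p = 0.195 with an estimated correlation). The neuropeptide-processing gene sbt-1 rose from 40.5 to 180 CPM and the neuropeptide gene flp-9 from 15.5 to 64.3. Intestinal genes were higher in 11 and lower in 0 of 15 cases, with a median of 1.61 (camera adjusted p = 0.00829; adjusted p = 0.195 with an estimated correlation). The metallothionein gene mtl-1 rose from 21.7 to 213 CPM and the filament gene ifb-2 from 23.8 to 95.9. Of 90 cuticle collagen genes, 53 were higher and 13 lower, or 52 and 13 adjusted over the list alone, with a median of 2.17 (camera adjusted p = 0.00066; adjusted p = 0.409 with an estimated correlation). Their sum rose from 13513 ± 740 to 103440 ± 5386 CPM, and col-124 and col-129 rose from 142 to 6824 and from 1.67 to 122. Of 36 genes of moulting and larval epidermis, 18 were higher and 8 lower, with a median of 1.14 (camera adjusted p = 0.221). The hedgehog-related gene grd-3 rose from 30.6 to 316 CPM. The 3 tested male-specific genes were higher, but together held only 1.17 ± 0.595 and 4.96 ± 1.47 CPM.

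Nuclear-encoded respiratory chain genes were higher in 58 and lower in 5 of 64 cases, and their sum rose from 7115 ± 136 to 12936 ± 213 CPM. Their median was 0.81 (camera adjusted p = 6.97e-05; adjusted p = 0.256 with an estimated correlation), but with total counts only it was 0.31, with 29 higher and 6 lower. The ATP synthase gene asb-2 rose from 75.1 to 332 CPM, while the complex I copy nduf-2.2 fell from 107 to 20.8. Of 12 genes encoded in mitochondrial DNA, 11 were higher and 0 lower, with a median of 2.14 (camera adjusted p = 0.00755; adjusted p = 0.48 with an estimated correlation). Genes of the tricarboxylic acid and glyoxylate cycles were higher in 20 and lower in 3 of 23 cases, with a median of 0.88 (camera adjusted p = 0.00755; adjusted p = 0.481 with an estimated correlation), led by idhg-2. With total counts only, 13 were higher and 3 lower, with a median of 0.39. Of 22 glycolysis genes, 16 were higher and 3 lower, with a median of 1.26 (camera adjusted p = 0.0178; adjusted p = 0.48 with an estimated correlation). The closely related genes gpd-1 and gpd-4 fell from 333 to 11.8 and from 202.3 to 9.66 CPM. Fatty acid beta-oxidation genes were higher in 26 and lower in 5 of 41 cases, with a median of 1.31 (camera adjusted p = 0.00755; adjusted p = 0.244 with an estimated correlation). The acyl-CoA dehydrogenase gene acdh-8 had 2 counts in wild type and 2781 in micu-1, a ratio of 1871 (95% counting interval 517.8 to 15450), and the acyl-CoA synthetase gene acs-2 rose from 67.2 to 573 CPM. Of 22 genes of fatty acid synthesis, 17 were higher and 3 lower, with a median of 0.96 (camera adjusted p = 0.0182; adjusted p = 0.394 with an estimated correlation). Calcium handling genes were higher in 10 and lower in 4 of 16 cases, or 11 and 4 adjusted over the list alone, with a median of 1.56 (camera adjusted p = 0.249). The muscle calsequestrin gene csq-1 rose from 47.3 to 336 CPM and the ER chaperone gene cnx-1 fell from 132 to 47.1. The 10 mitochondrial dynamics genes were called 4 higher and 5 lower, and their median of -0.46 and mean of 0.81 differed in sign (camera adjusted p = 0.717).

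Of 128 cytochrome P450 and UDP-glucuronosyltransferase genes, 10 were lower in micu-1 and 14 not called, and the others were higher, with a median of 1.69 (camera adjusted p = 3.3e-07; adjusted p = 0.0497 with an estimated correlation). These detoxification genes included ugt-62, which rose from 59.1 ± 4.76 to 1317 ± 83.5 CPM, and cyp-14A1, from 6.35 to 120. Oxidative stress and glutathione genes were higher in 38 and lower in 7 of 53 cases, with a median of 1.62 (camera adjusted p = 0.00126; adjusted p = 0.213 with an estimated correlation). The SKN-1 target gst-4 rose from 65.9 ± 2.50 to 611 ± 4.47 CPM (3.21, adjusted p = 4.84e-16) and gst-14 from 0.540 to 55.7. Of 11 targets of the insulin-regulated factor DAF-16, 9 were higher and 2 lower, with a median of 1.30 (camera adjusted p = 0.0182; adjusted p = 0.195 with an estimated correlation). Among these, gpd-2 rose from 112.8 to 1083 CPM, scl-20 from 1.88 to 33.4 and sod-3 from 0.602 to 22.2. Hypoxia genes were higher in 6 and lower in 1 of 10 cases (median 1.07, camera adjusted p = 0.105, but 0.0464 with the filter at a CPM of 5, range 0.0464 to 0.158), and the ferritin gene ftn-1 rose from 39.5 to 360 CPM.

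C-type lectin genes were higher in 82 and lower in 13 of 107 cases, with a median of 1.74 (camera adjusted p = 7.61e-05; adjusted p = 0.0749 with an estimated correlation). The smallest adjusted p values belonged to 2 that fell, clec-87 from 3493 ± 84.7 to 58.2 ± 3.78 CPM and clec-88 from 493 to 5.29. Of 64 antimicrobial effector genes, 38 were higher and 13 lower, with a median of 1.06 (camera adjusted p = 0.0515). That list was called in 6 of 14 alternatives (range 0.00447 to 0.108), among them those without wild type replicate 3 (0.0409), without micu-1 replicate 1 (0.044) or 2 (0.046), and without micu-1;mcu-1 replicate 1 (0.0355) or 3 (0.0372). The lysozyme gene lys-4 fell from 188 to 5.23 CPM and lys-2 rose from 171 to 1228. Intracellular pathogen response genes were higher in 9 and lower in 0 of 12 cases (median 1.99, camera adjusted p = 0.0683), with pals-34 at 2.08 and 11.015 CPM. The yolk protein genes were called 3 higher and 2 lower of 6. Their median of 0.24 and mean of -0.12 differed in sign, and the median turned to -0.25 with total counts only and to -0.01 with total counts without ribosomal RNA genes (camera adjusted p = 0.996). Of these, vit-3 fell from 9231 to 2198 CPM and vit-6 rose from 18294 to 31453.

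The comparison of micu-1;mcu-1 with micu-1 addressed what loss of the uniporter pore adds when its regulator is already missing. The double mutant had more oocyte and eggshell transcripts than micu-1, and somewhat fewer sperm transcripts. Several lysosomal lipase and protease genes and antimicrobial genes were higher. Among genes with a class name, argk-1, clec-258 and clec-218 had the largest decreases that met the rule for naming. At an adjusted p under 0.05, edgeR called 1080 genes, 799 higher and 281 lower, of which 320 changed over 2-fold. The samples did not overlap for 1063 of these calls, and for 26.28% of tested genes, where chance gives 10%. With total counts only, 696 genes were called and 35.92% of them were higher, against 73.98% with TMM scaling. Total counts without ribosomal RNA genes called 973, of which 66.6% were higher. Without micu-1 replicate 1, 2 or 3, the count was 716, 644 or 647.

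Of 26 genes of oocytes, eggshell and germline, 20 were higher and 0 lower in micu-1;mcu-1 than in micu-1, or 23 and 0 adjusted over the list alone. Their sum was 5179 ± 635 against 3724 ± 206 CPM, and their median log2 fold change was 1.12 (camera adjusted p = 2.81e-25; adjusted p = 0.151 with an estimated correlation). The gene puf-5 rose from 15.7 ± 1.75 to 63.98 ± 4.05 CPM (2.03, SE 0.12, adjusted p = 1.95e-10), cpg-3 from 18.1 to 68.8 (adjusted p = 2.22e-09) and egg-1 from 11.02 to 37.2 (adjusted p = 3.78e-09). These levels stayed far under those of wild type, at 873, 1262 and 578 CPM. Sperm genes were lower in 11 and higher in 2 of 80 cases, or 22 and 2 adjusted over the list alone, with a median of -0.36 (camera adjusted p = 1.13e-06; adjusted p = 0.457 with an estimated correlation). The member with the smallest adjusted p, ssp-37, was higher, at 19.96 against 9.83 CPM, while msp-10 was lower, at 76.8 against 118.9. Early embryo genes (0 higher, 1 lower, camera adjusted p = 0.69) and histone genes (0 higher, 3 lower, or 0 and 0 adjusted over the list alone, camera adjusted p = 0.0984) were not called as lists. The histone list was called lower without micu-1;mcu-1 replicate 1 (median -0.31, adjusted p = 0.0427) and without replicate 2 (-0.38, adjusted p = 0.0329, range 0.0329 to 0.976). The histone median of -0.18 and mean of 0.02 differed in sign and the median was near 0 with the filter at a CPM of 5, and the early embryo median of -0.01 turned to 0.01 with RLE size factors.

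The largest fitted increases among genes with a class name that met the rule for naming were rgs-9, lbp-3, ztf-25, lys-3 and haf-6. The ranks of rgs-9 and ztf-25 are uncertain, since they had 0 and 2 counts in micu-1. The fatty acid-binding protein gene lbp-3 (chromosome X, 3257372 to 3258155) rose from 4.36 ± 0.711 to 142 ± 39.6 CPM (log2 fold change 5.04, SE 0.20, adjusted p = 8.36e-12), above the wild-type level of 44.5. The transporter gene haf-6 (chromosome I) rose from 3.69 ± 0.693 to 32.5 ± 5.36 CPM (3.12, adjusted p = 1.34e-10), and the lysozyme gene lys-3 from 1.29 to 15.9 (3.62, adjusted p = 2.38e-07). The gene rgs-9 had 0 counts in micu-1 and 10 in micu-1;mcu-1, at least 4.235-fold more, and ztf-25 had 2 and 60 counts, a ratio of 38.11 (95% counting interval 10.55 to 314.7). Among genes with a sequence name only, F56A4.3 (chromosome V, 2453414 to 2456147) rose from 0.874 ± 0.282 to 112 ± 35.1 CPM (6.95, SE 0.26, adjusted p = 7.66e-12), with 32.6 ± 0.961 in wild type. The arginine kinase gene argk-1 (chromosome V, 16103894 to 16105952) had the largest decrease among genes with a class name that met the rule for naming, from 147 ± 2.44 to 11.6 ± 1.94 CPM (-3.66, SE 0.13, adjusted p = 9.19e-14), under the 31.7 of wild type. It was followed by clec-258, from 109 to 14.3 CPM, and clec-218, from 440 to 92.5. The next were nhr-202, scl-24, wago-10, cth-1, sams-5, cls-3 and gst-14. Of these, the cystathionine gamma-lyase gene cth-1 fell from 467 ± 38.7 to 159 ± 20.9 CPM, near the 144 ± 2.99 of wild type, and the S-adenosylmethionine synthetase gene sams-5 from 11.7 to 4.07.

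**Figure D4:**
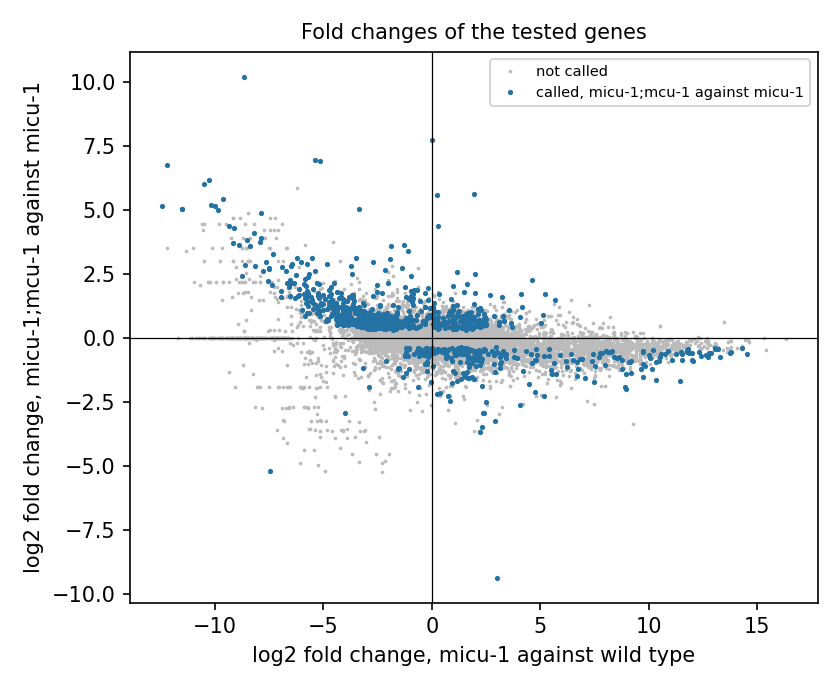
Log2 fold change of each tested gene in micu-1 against wild type (horizontal axis) and in micu-1;mcu-1 against micu-1 (vertical axis), with genes called in the latter in blue and the others in grey. Of the 1080 called genes, 837 moved opposite to their change in micu-1 and 177 in the same direction, where the shared micu-1 samples alone push the axes in opposite directions.

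Lysosomal hydrolase genes were higher in 9 and lower in 0 of 24 cases in micu-1;mcu-1, with a median of 0.18 that turned to -0.04 with total counts only (camera adjusted p = 8.91e-05; adjusted p = 0.457 with an estimated correlation). The lipase gene lipl-5 rose from 361 ± 72.1 to 1277 ± 168 CPM (1.82, adjusted p = 1.29e-08), the cathepsin gene cpr-4 from 126 to 426 and cpr-1 from 32.97 to 107. Endosome-lysosome fusion genes had a median of 0.22, with 2 higher and 0 lower (camera adjusted p = 0.0285; adjusted p = 0.457 with an estimated correlation). That call was lost in 4 of 14 alternatives, among them those without micu-1 replicate 1 (adjusted p = 0.0573) and without micu-1;mcu-1 replicate 3 (adjusted p = 0.113, range 0.0051 to 0.113). The members called were vps-39, at 45.8 ± 9.81 against 30.9 ± 3.04 CPM (0.56, adjusted p = 0.0106), and vps-33.2, at 22.95 against 15.9 (0.53, adjusted p = 0.0207). The vps-39 call was lost with total counts only (adjusted p = 0.271), without micu-1 replicate 2 (0.0526) and without micu-1 replicate 3 (0.0792, range 0.000318 to 0.271). The vps-33.2 call was lost with total counts only (0.338), without micu-1 replicate 1 (0.115) or 3 (0.119) and without micu-1;mcu-1 replicate 2 (0.134, range 0.00591 to 0.338). The vacuolar proton pump list was lower, with a median of -0.25 and 0 members higher and 2 lower, or 2 and 11 adjusted over the list alone (camera adjusted p = 0.00189; adjusted p = 0.457 with an estimated correlation). The list of autophagy and mitophagy was not called (median 0.08, and -0.13 with total counts only; camera adjusted p = 0.367). Its members lgg-1 (0.12, adjusted p = 0.64), bec-1 (0.22, adjusted p = 0.435) and sqst-1 (0.09, adjusted p = 0.77) were not called, nor was the lyase gene spl-1 (0.04, adjusted p = 0.882). The gene hlh-30 was lower (-0.42, adjusted p = 0.0487), but 12 of 21 alternatives lost that call (range 0.0284 to 0.241). They include those without wild type replicate 2 (0.0647), without micu-1 replicate 1 (0.0705), 2 (0.241) or 3 (0.113) and without micu-1;mcu-1 replicate 1 (0.0772), 2 (0.156) or 3 (0.0653).

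Antimicrobial effector genes were higher in 15 and lower in 3 of 64 cases in micu-1;mcu-1, or 19 and 3 adjusted over the list alone. Their median of 0.14 turned to -0.09 with total counts only (camera adjusted p = 0.0285; adjusted p = 0.616 with an estimated correlation). That call was lost in 3 of 14 alternatives, among them those without micu-1 replicate 1 (adjusted p = 0.101) and without micu-1;mcu-1 replicate 1 (0.314, range 0.000834 to 0.314). Beside lys-3, the caenopore gene spp-2 rose from 69.4 to 182 CPM. Of 107 C-type lectin genes, 23 were higher and 7 lower, or 25 and 9 adjusted over the list alone, with a median of 0.05 that turned to -0.17 with total counts only (camera adjusted p = 0.253), and the filter at a CPM of 5 called it higher (0.0384, range 0.0384 to 0.671). Here clec-87 rose from 58.2 to 251 CPM, and clec-258 fell. Fatty acid synthesis genes were higher in 5 and lower in 1 of 22 cases, or 8 and 1 adjusted over the list alone, with a median of 0.15 that turned to -0.06 with total counts only (camera adjusted p = 0.0847). That list was called higher without micu-1 replicate 2 (0.0457) and without micu-1;mcu-1 replicate 2 (0.0381, range 0.0381 to 0.164). The desaturase gene fat-5 rose from 21.995 to 53.3 CPM (1.28, adjusted p = 3.29e-06). Sphingolipid genes were 5 higher and 2 lower, and their median of 0.03 turned to -0.18 with total counts only and to -0.01 with total counts without ribosomal RNA genes (camera adjusted p = 0.44). The glucosylceramidase genes gba-4 and gba-2 moved apart, from 9.96 to 59.9 and from 58.0 to 26.7 CPM. Of the DAF-16 targets, 4 were higher and 1 lower, or 5 and 3 adjusted over the list alone, with a median of 0.06 that turned to -0.15 with total counts only (camera adjusted p = 0.118). Among them, scl-20 rose from 33.4 to 112 CPM and mtl-1 from 213 to 389.

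Small shifts to lower levels passed camera in micu-1;mcu-1 for the nuclear-encoded respiratory chain (median -0.14, adjusted p = 0.000405; adjusted p = 0.457 with an estimated correlation) and cytosolic ribosomal proteins (-0.17, adjusted p = 1.13e-06; adjusted p = 0.595 with an estimated correlation). The called members were nuo-5 and rpl-11.2, both lower. The nuo-5 call was lost without micu-1 replicate 1 (0.0509), 2 (0.0728) or 3 (0.0545) and without micu-1;mcu-1 replicate 2 (0.0753, range 0.00265 to 0.0753), and the rpl-11.2 call without micu-1 replicate 3 (0.0686, range 0.00069 to 0.0686). The ER unfolded protein response was lower in 4 and higher in 0 of 13 cases, with a median of -0.13 (camera adjusted p = 0.0218; adjusted p = 0.457 with an estimated correlation), a call lost without micu-1;mcu-1 replicate 1 (0.0712, range 0.0061 to 0.0712). The protein disulfide isomerase gene pdi-2 fell from 559 to 395 CPM. In the calcium handling list, with 0 higher and 2 lower of 16, the calreticulin gene crt-1 fell from 500 to 349 CPM. Mitochondrial ribosomal protein, muscle and neuronal lists had medians of -0.12, -0.16 and -0.16 (camera adjusted p = 0.0116, 0.0175 and 0.0175; adjusted p = 0.457, 0.611 and 0.549 with an estimated correlation). Leaving out 1 sample ended each of these calls. Mitochondrial ribosomal proteins lost theirs without micu-1 replicate 1 (0.0528) or micu-1;mcu-1 replicate 3 (0.076, range 0.00178 to 0.076), muscle without micu-1;mcu-1 replicate 2 (0.222, range 0.00294 to 0.222), and neurons without micu-1 replicate 3 (0.0616) or micu-1;mcu-1 replicate 3 (0.113, range 0.00369 to 0.113). The tricarboxylic acid cycle list (median -0.15, camera adjusted p = 0.0285; adjusted p = 0.634 with an estimated correlation) lost its call in 5 of 14 alternatives, among them those without micu-1 replicate 1 (0.0528) or 2 (0.0835) and without micu-1;mcu-1 replicate 2 (0.384, range 0.000834 to 0.384). In all, 13 of 36 lists were called, 4 higher and 9 lower, against 0 by camera with an estimated correlation and 9 by fry. The fry calls were not a subset. They included the mitochondrial unfolded protein response (fry adjusted p = 0.0443), mitochondrial dynamics (0.0264), sphingolipids (0.0188) and DAF-16 targets (0.0188). Lists that fry did not call included the respiratory chain (0.0734) and cytosolic ribosomal proteins (0.132). The lists of calcium handling, mitochondrial DNA, the mitochondrial unfolded protein response, heat shock, oxidative stress, detoxification, beta-oxidation, glycolysis, intracellular pathogen response, hypoxia, yolk proteins, cuticle collagens, moulting, intestine and mitochondrial dynamics were not called (camera adjusted p = 0.0715 to 0.932). Of these, heat shock was called lower in 5 of 14 alternatives, those without wild type replicate 1 (0.0362), 2 (0.0443) or 3 (0.0413), micu-1 replicate 2 (0.0457) or micu-1;mcu-1 replicate 3 (0.014, range 0.014 to 0.243). Glycolysis was called lower in 3, with the filter at a CPM of 5 (0.019), with total counts without ribosomal RNA genes (0.0333) and without micu-1;mcu-1 replicate 3 (0.00386, range 0.00386 to 0.384). In 1 alternative each, calcium handling was called without micu-1;mcu-1 replicate 3 (0.0191, range 0.0191 to 0.277), yolk proteins without replicate 2 (0.019, range 0.019 to 0.504), collagens without replicate 1 (0.0384, range 0.0384 to 0.315) and the mitochondrial unfolded protein response with the filter (0.0382, range 0.0382 to 0.236). The proteasome list was not called either (median 0.04, and -0.19 with total counts only; camera adjusted p = 0.843). The chaperone gene hsp-60 was lower (-0.39, adjusted p = 0.0302), a call lost in 8 of 21 alternatives (range 0.00161 to 0.115). They include those without wild type replicate 2 (0.05), without micu-1 replicate 1 (0.095), 2 (0.115) or 3 (0.0994) and without micu-1;mcu-1 replicate 1 (0.104) or 2 (0.101). The genes hsp-6 (-0.21, adjusted p = 0.292), hsp-4 (-0.23, adjusted p = 0.351) and gst-4 (0.07, adjusted p = 0.781) were not called.

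Of the 12289 genes called in micu-1 against wild type, 837 changed in the opposite direction in micu-1;mcu-1 against micu-1, 177 in the same direction, and 11275 were not called there. Among genes lower in micu-1, 616 of 5571 (11.06%) were called higher in the double mutant, where independent lists would give 305.91. Among genes higher in micu-1, 221 of 6718 (3.29%) were called lower, where independent lists would give 129.73. The gap between these percentages thus partly reflects the balance of calls between the mutants, 799 higher and 281 lower. The split into 616 and 221 was not computed under other scalings. With total counts only, the balance of calls between the mutants turned to 250 higher and 446 lower. Oocyte genes such as puf-5, cpg-3 and egg-1 were among the 616, and argk-1, cth-1 and gst-14 among the 221. Independent lists of these sizes would share 435.64 genes with opposite directions, and the count was 501, 508, 562 and 586 without micu-1 replicate 2, micu-1 replicate 3, micu-1 replicate 1 and micu-1;mcu-1 replicate 2, and 522 with total counts only. The number for independent lists was not computed for these settings. Both comparisons use the same micu-1 samples. Across genes their log2 fold changes correlated with r = -0.3536 (covariance -0.8176), against -0.5137 to -0.4496 (mean covariance -0.05341) in 20 simulations with no change. The observed r was thus weaker than every simulated r. The simulations gave all samples the mean levels of micu-1, so genes near 0 there could fall under the filter, while they stay in the observed value. The difference of -0.7642 in covariance is therefore not a full correction for the shared samples. The overlap of 837 genes has no correction for shared samples, and part of its excess may come from the shared libraries, since 3 samples cannot be divided into 2 sets of at least 2.

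The comparison of micu-1;mcu-1 with wild type addressed whether the double mutant still differed from wild type. The double mutant resembled micu-1, with far more sperm transcripts and far fewer transcripts of oocytes and early embryos than wild type. The lists of proteasome and autophagy genes were called lower by camera, but with an estimated correlation only autophagy was (adjusted p = 0.067 and 0.0426). As in micu-1, a smaller share of oocyte and embryo transcripts was not tested as the source of these falls. The lists of muscle, neuronal, intestinal and detoxification genes were called higher, but with an estimated correlation only the last of these was (adjusted p = 0.229, 0.201, 0.186 and 0.0426). The edgeR test called 12201 genes, 6600 higher and 5601 lower, and 10291 of them changed over 2-fold. The balance turned to 4768 higher and 6681 lower with total counts only, and to 5981 and 6065 with total counts without ribosomal RNA genes. The samples did not overlap for 11820 of these calls, and for 83.58% of tested genes, where chance gives 10%. Of the 12289 genes called in micu-1, 11615 (94.52%) were called in the same direction here, 20 in the opposite direction and 654 not at all, where independent lists would share 5191.5 in the same direction. Both comparisons use the same wild-type samples. The correlation across genes was 0.9789 (covariance 10.37), against 0.4389 to 0.5148 (mean covariance 0.04471) in the simulations. These gave all samples the mean levels of wild type, so genes near 0 there could fall under the filter. The difference of 10.32 in covariance is therefore not a full correction for the shared samples. Part of the excess in the overlap of 11615 genes may come from the shared libraries.

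Sperm genes summed to 10479 ± 1246 CPM in micu-1;mcu-1, with 74 higher and 4 lower than in wild type and a median log2 fold change of 9.30, or 8.55 with genes at 0 counts at their bound (camera adjusted p = 1.51e-15; adjusted p = 0.067 with an estimated correlation). The gene msp-51 was at least 13090-fold higher. Oocyte and eggshell genes were lower in 25 of 26 cases, with a median of -3.49 (camera adjusted p = 6.95e-10; adjusted p = 0.17 with an estimated correlation), and cpg-1 stood at 150 ± 15.6 against 2408 ± 50.3 CPM. Early embryo genes were lower in 11 of 12 cases, with a median of -5.84, or -5.69 at their bounds (camera adjusted p = 0.000312; adjusted p = 0.0964 with an estimated correlation). The proteasome list was lower in 32 of 33 cases (median -1.66, camera adjusted p = 1.62e-09; adjusted p = 0.067 with an estimated correlation). Autophagy genes were lower in 29 and higher in 1 of 35 cases (median -0.9998, camera adjusted p = 4.58e-05; adjusted p = 0.0426 with an estimated correlation), and endosome-lysosome fusion genes in 17 and 1 of 19 (median -1.24, camera adjusted p = 0.000462; adjusted p = 0.177 with an estimated correlation). The gene vps-39 was lower than in wild type (-1.89, SE 0.13, adjusted p = 3.52e-11), as were bec-1 (-0.73, adjusted p = 0.000112) and hsp-4 (-2.01, adjusted p = 2.43e-11). The gene lgg-1 was lower (-0.29, adjusted p = 0.0275), a call lost in 4 of 21 alternatives, among them those without wild type replicate 3 (0.0961) and without micu-1;mcu-1 replicate 3 (0.119, range 2.31e-06 to 0.996). The gene sqst-1 was higher (0.73, adjusted p = 8.6e-05), but not with total counts only (0.01, adjusted p = 0.963, range 4.11e-08 to 0.963). For spl-1, at 56.95 ± 4.56 CPM, no change was called (-0.11, adjusted p = 0.376), except that total counts only gave -0.82 (adjusted p = 3.64e-05) and total counts without ribosomal RNA genes -0.40 (adjusted p = 0.00261, range 3.64e-05 to 0.749).

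All 25 muscle genes were higher in micu-1;mcu-1 than in wild type (median 2.49, camera adjusted p = 3.06e-07; adjusted p = 0.229 with an estimated correlation), with myo-3 at 219 ± 32.4 against 27.1 ± 1.79 CPM. Neuronal genes were higher in 41 and lower in 1 of 50 cases (median 1.71, camera adjusted p = 7.29e-05; adjusted p = 0.201 with an estimated correlation). Cytochrome P450 and UDP-glucuronosyltransferase genes were higher in 102 and lower in 9 of 128 cases (median 1.82, camera adjusted p = 1.5e-07; adjusted p = 0.0426 with an estimated correlation). From the oxidative stress and glutathione list, gst-4 stood at 640 ± 68.5 against 65.9 ± 2.50 CPM. Respiratory chain genes were higher in 56 and lower in 5 of 64 cases, with a median of 0.70 that turned to -0.01 with total counts only (camera adjusted p = 0.000312; adjusted p = 0.282 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 70 and higher in 3 of 82 cases, or 71 and 3 adjusted over the list alone (median -0.39, camera adjusted p = 7.29e-05; adjusted p = 0.526 with an estimated correlation), a call lost with the filter at a CPM of 5 (0.115, range 1.08e-06 to 0.115). Antimicrobial effectors (median 1.19, camera adjusted p = 0.00934; adjusted p = 0.515 with an estimated correlation) and intracellular pathogen response genes (median 2.02, camera adjusted p = 0.0279; adjusted p = 0.229 with an estimated correlation) were higher as lists, with 38 and 10 members called higher and 9 and 0 lower. Also higher were the lists of C-type lectins, lysosomal hydrolases, oxidative stress, beta-oxidation, fatty acid synthesis, mitochondrial DNA, cuticle collagens, intestine, the tricarboxylic acid cycle, glycolysis and DAF-16 targets (camera adjusted p = 5.03e-05 to 0.0295; adjusted p = 0.067 to 0.526 with an estimated correlation). With total counts only, the tricarboxylic acid cycle list had a median of 0.04, with 6 higher and 4 lower, against 0.75, 19 and 3 with TMM scaling. Glycolysis lost its call with total counts without ribosomal RNA genes (0.0561, range 0.00809 to 0.0561), and with total counts only its median was 0.40. Lists of histones, the ER unfolded protein response and mitochondrial ribosomal proteins were lower (camera adjusted p = 0.00169, 0.00123 and 7.29e-05; adjusted p = 0.371, 0.171 and 0.177 with an estimated correlation). The lists of the vacuolar proton pump, sphingolipids, hypoxia, yolk proteins, moulting, the mitochondrial unfolded protein response, heat shock, calcium handling and mitochondrial dynamics were not called (camera adjusted p = 0.126 to 0.758). With the filter at a CPM of 5, the vacuolar proton pump (0.0218, range 0.0218 to 0.49) and hypoxia (0.0415, range 0.0415 to 0.202) were called higher. The pump median of 0.52 turned to -0.18 with total counts only, with 2 members higher and 8 lower. In all, 27 of 36 lists were called, 18 higher and 9 lower, against 2 with an estimated correlation. A list called here and not in micu-1 is not shown to differ between the mutants.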

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

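The alternatives without ribosomal RNA genes, with total counts without ribosomal RNA genes and with summed copies were chosen after the results were seen. The count of genes called in micu-1 against wild type (12289) stayed within 1.5 times under every alternative run, as did that in micu-1;mcu-1 against wild type (12201). Leaving out each sample gave 12013 to 12648 and 11936 to 12336. The count in micu-1;mcu-1 against micu-1 (1080) fell to 696 with total counts only, where 250 were higher. With total counts without ribosomal RNA genes it was 973, of which 66.6% were higher. Counts of ribosomal RNA genes thus accounted for most of that fall. The cause of the rest was not tested. Leaving out each sample gave 644 to 1136, with the lowest counts without micu-1 replicate 1 (716), 2 (644) or 3 (647). The cause was not tested. Without micu-1;mcu-1 replicate 1, 2 or 3, which leaves as many samples, 1030, 757 and 1136 were called.

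The 837 genes that changed in opposite directions in micu-1 and micu-1;mcu-1 became 522 with total counts only, whose cause was not tested, and 501 to 857 when each sample was left out. The 11615 genes called in the same direction in both mutants against wild type became 11390 to 11595, and the percent of calls between the mutants that were opposite (77.5) became 73.77 to 80.19, and 75 to 78.94 under the other alternatives. With an estimated correlation, the number of lists called by camera fell from 26 to 2 for micu-1 against wild type, from 13 to 0 for micu-1;mcu-1 against micu-1 and from 27 to 2 for micu-1;mcu-1 against wild type. The estimated correlation alone does not account for this fall. In micu-1 against wild type, autophagy had an estimated correlation of -0.0094, under the preset 0.01. Its adjusted p still rose from 3.61e-05 to 0.0497. Other differences between the camera settings were not tested. Fry called 35, 9 and 34. Leaving out each sample gave 25 to 27, 9 to 14 and 27 lists.

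Replicate numbers did not pair the samples. The residual correlations of same-number pairs were -0.045 to 0.0075, against -0.0329 to 0.0422 for other pairs. With the replicate number as a block, 12111, 853 and 12008 genes and 25, 11 and 27 lists were called, which has fewer degrees of freedom.

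Some values of named genes and lists changed sign, and the cause was not tested. In 5 cases the value was called before or after. With a filter at a CPM of 5, cytosolic ribosomal proteins in micu-1 against wild type turned from -0.26 to 0.0506 and hsp-60 from -0.01 to 0.31. In micu-1;mcu-1 against wild type, total counts only turned hlh-30 from 0.17 to -0.55 and hsp-6 from 0.01 to -0.71, and total counts without ribosomal RNA genes turned hsp-6 to -0.28. The other changes of sign were of values not called on either side.

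Among these, in micu-1 against wild type, the filter turned mcu-1 to 0.0723 and spl-1 to 0.1688, total counts only turned hsp-6 to -0.2729, total counts without ribosomal RNA genes turned hsp-6 to -0.0257 and yolk proteins to -0.0062, a fit of only the groups compared turned hsp-60 to 0.0025, and the replicate block turned heat shock to 0.0667. In micu-1;mcu-1 against micu-1, size factors as in DESeq2 turned beta-oxidation to 0.0196, early embryo to 0.0097, sbt-1 to 0.0078 and the mitochondrial gene at 7827 to 9428 to 0.0349, and DESeq2 turned the last pair to 0.0077 and 0.0349. Total counts only turned gst-4 to -0.1379, lgg-1 to -0.0983, spl-1 to -0.1776, sqst-1 to -0.1226 and vit-6 to -0.178. Total counts without ribosomal RNA genes turned sphingolipids to -0.0143, proteasome to -0.0123, spl-1 to -0.0012 and vit-6 to -0.0016, and the filter turned histones to 5e-04. In micu-1;mcu-1 against wild type, the filter turned spl-1 to 0.1862, and total counts without ribosomal RNA genes turned hlh-30 to -0.1276 and the mitochondrial unfolded protein response to -0.121. Size factors as in DESeq2 and DESeq2 turned hsp-6 to -0.0409, no filter to -0.0494 and leaving out ribosomal RNA genes to -0.0091.

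Leaving out each sample gave values on both sides of 0, or at 0, for the results below. In micu-1 against wild type these were heat shock (-0.825 to 1.148) and hsp-60 (-0.0777 to 0.0169), and in micu-1;mcu-1 against wild type heat shock (-0.7799 to 0.4348) and hsp-6 (-0.0687 to 0.111). In micu-1;mcu-1 against micu-1 they were mitochondrial DNA (-0.1954 to 0.2766), detoxification (0 to 0.07), sphingolipids (-0.1068 to 0.0855), beta-oxidation (-0.0254 to 0.0365), C-type lectins (-0.0538 to 0.0738), intracellular pathogen response (-0.0413 to 0.3346), early embryo (-0.3351 to 0.0823), proteasome (-4e-04 to 0.053), gst-4 (-0.0204 to 0.1322), spl-1 (-0.0292 to 0.1077), sqst-1 (-0.0208 to 0.1995), vit-6 (-0.0311 to 0.1461) and the mitochondrial gene (-0.1381 to 0.0875).

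In all, 72 values changed sign or reached 0, 6233 kept their direction and side of the threshold, 72 kept their direction and lost their call, and 44 kept their direction and gained one. Medians of lists under total counts only, where no list test was run, are not among these, nor is that of the intracellular pathogen response between the mutants, which the filter turned from 0.1579 to -0.2377. Depth limits genes with 0 to 3 counts in a group, such as msp-51 and acdh-8, to bounds or wide intervals.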

Other observations

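The test for swapped samples and both tests on muscle, neuron and intestine genes were chosen after the results were seen. Some of the largest changes fell on genes known only by a sequence name. F26B1.8 and C48E7.7 had 0 counts in wild type and were at least 4173-fold and at least 4085-fold higher in micu-1. C17E7.4 had 0 counts in micu-1 and was at least 574.6-fold lower there than in wild type, with 31 counts in micu-1;mcu-1, at least 13.13-fold more than in micu-1. Of the 1080 genes called between the mutants, 66 (6.11%) were not called in micu-1 against wild type.

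Genes called between micu-1;mcu-1 and micu-1 were counted in windows of 1 Mb, and these are high windows picked after their values were seen. On chromosome V between 2 and 3 Mb, where F56A4.3 lies, 21 of 94 tested genes were called (22.34%), and on chromosome IV between 12 and 13 Mb, 28 of 169 (16.57%), against 7.422% of all tested genes. The next window on chromosome IV, from 13 to 14 Mb, holds micu-1 and had 17 of 145 called (11.72%). No test was run on these windows, so they do not show that the calls are spread unevenly.

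Sperm genes were higher and oocyte genes lower in both mutants than in wild type. A swap of samples between wild type and the mutants was argued against, since the lowest wild-type micu-1 level was 24.17 times the highest mutant level. Unequal shares of ribosomal RNA were argued against too, since over the scalings tested the sperm median of fitted values never fell under 8.76 and the oocyte median never rose over -3.49. With genes at 0 counts at their bound, the sperm median in micu-1;mcu-1 was 8.55 under TMM scaling, and this was not tested under the other scalings. A younger stage of the mutant animals at collection may account for the pattern, since the moulting list had medians of 1.14 in micu-1 and 0.99 in micu-1;mcu-1 and the early embryo list -6.46 and -5.84, although members of the moulting list moved both ways, its list test did not pass, and its median in micu-1;mcu-1 was 0.33 with total counts only. The yolk protein genes, expressed in adults, did not go that way in sum under TMM scaling. They had 72914 ± 2676 CPM in wild type, 90220 ± 5231 in micu-1 and 98936 ± 12970 in micu-1;mcu-1. However, vit-3 fell and their median turned with the scaling. With total counts only, 1 yolk gene was called higher and 3 lower in micu-1, and 0 and 4 in micu-1;mcu-1. The direction of the yolk genes thus depended on the scaling. A younger stage therefore stays open. The yolk sum, which adult hermaphrodites make and males do not, argues against males as most of the mutant animals. The 3 tested male-specific genes, with medians of 2.67 and 1.53, lay near the floor. A smaller share of males therefore cannot be told apart from a younger stage. A direct effect of micu-1 loss on the germline stays open and untested.

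Genes called between the mutants moved mostly towards wild type. A partial return along the axis from wild type to micu-1 is a candidate explanation, since 80.45, 81.21 and 81.61% of the calls moved that way when the sign was taken from a micu-1 sample left out of the test, against 62.4, 62.55 and 61.72% of all tested genes. A double mutant collected at a slightly different stage could give the same picture and was not tested. An excess of calls from background linked to the mcu-1 allele was argued against, since within 2 Mb of mcu-1 49 of 652 genes were called and elsewhere 1031 of 13899 (odds ratio 1.014, 95% interval 0.7369 to 1.369, Fisher exact p = 0.939). Background elsewhere, including near micu-1 on the same chromosome, was not tested, and this count cannot exclude single linked variants.

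Most muscle, neuron and intestine genes were called higher in both mutants. With an estimated correlation, camera called none of these lists (adjusted p = 0.186 to 0.256). Scaling was argued against, since the lowest of the medians over the scalings tested was 0.80. The lists did not rise alike. The lower quartile of the muscle list lay over the upper quartiles of the neuron and intestine lists by 0.22 in micu-1 and 0.25 in micu-1;mcu-1. This argues only against an equal rise of all listed genes from a smaller share of germline and embryo RNA. Members also expressed in germline or embryo would rise less, and this was not checked. Such a smaller share may account for part or all of the rise, and the stage of the animals stays open.

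The 6 samples of each comparison can be divided into 3 and 3 in 10 ways, which is too few for a share under 0.05, with 1 division reaching the real count each time. For genes, the real divisions gave 12289, 1080 and 12201 calls and the highest others 0, 1 and 0. For lists, they gave 26, 13 and 27, and the highest others 23, 9 and 25. The other divisions mix samples of both groups. In the comparisons with wild type, these divisions called 0 genes but still 16 to 23 lists for micu-1 and 17 to 25 for micu-1;mcu-1. Each mixed division keeps part of the difference between the groups and widens the spread within its sides. Its calls are thus not counts under no difference. These divisions therefore cannot decide how many genes or lists would be called by chance.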
